A study of Homo sapiens with 2 samples.

How the data were processed

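RNA from 1 sample of parental SBC5 cells and 1 of cisplatin-resistant SBC5 cells was compared. Per the labels' protocols, RNA was purified from cells grown in serum-supplemented medium and polyadenylated RNA was made into strand-preserving libraries. The deposited table gave FPKM, fragments scaled to the length of a locus and to library size, in 1 column per library, per the file headers. TopHat2, with no version given, and the genome build hg38 were named per the submitters' processing notes. The program and annotation behind the FPKM are not given in the sources used here. Columns were matched to libraries by the sample descriptions in the labels, and 0 columns were left unmatched.

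The table held 19217 loci, of which 2919 had no gene name, 23 had a name that a spreadsheet had turned into a date, and 193 joined several symbols. These unnamed and date-named loci were left out, joined loci were kept under their joined name, and names were used as the table gives them. Of 12494 names, 2282 had several loci, and the locus with the highest mean FPKM stood for the name. The order of the loci showed 3 parts on each chromosome, and annotated strands placed 12938 loci in a plus or minus part, where 98.7% of the 11779 with an annotated strand lay on that strand, and 6279 in a part of no strand. This assignment was inferred from the order and is not recorded in the table. Loci without a strand can be short pieces with very high FPKM, so the strand-assigned locus, where there was one, is given beside a named gene that such a locus represents. They stood for 414 of the genes compared.

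Genes with at least 1 FPKM in either library were compared, 12405 in all. The log2 ratio was log2 of resistant FPKM plus 1 over parental FPKM plus 1, on the deposited scaling. No test was possible with 1 library per group, so no p-value was computed. A fixed rule of size, a log2 ratio of at least 1 or at most -1, replaced a test. The range of genes of like level was taken in 20 bins of mean level. Depth could not be recovered: the table holds no counts. Among 7591 loci above 0 and under 5 FPKM in both libraries, 52.9% had a ratio equal, within a relative tolerance of 2e-05, to a ratio of whole numbers up to 20 times the single factor 0.996, against 0.478% on average with 20 wrong factors. This gives the relative worth of 1 read. It does not give the number of reads behind a value, since few or many reads can give the same ratio. Values that rest on few reads could therefore not be marked out with certainty, though a ratio of small whole numbers makes few reads likely.

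Before the data were examined, 54 gene lists were fixed, and 48 had at least 5 measured members. Each list's median log2 ratio was placed among 10000 random lists of the same size drawn from the same level bins, and a list stood apart at percentile 98 or above or 2 or below. Percentiles describe these libraries, since members of a list are not independent. Gene positions came from GENCODE release 29, whose build is the same as hg38, for 11706 genes matched by symbol. Medians were taken per chromosome and in runs of 50 neighbouring genes, with a 95% interval of the median from order statistics, and 100 shuffles within level bins gave a range without position. Shuffles under the alternatives were chosen after seeing the data.

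Genes were named by a rule fixed beforehand: the 15 highest and 15 lowest log2 ratios apart from small RNA genes, up to 4 members of each list at or past 1 or -1 by size, and 42 genes of cisplatin response and lung cancer at any level. Of these 42, 9 had no locus of that name and were not analysed here. Some genes that the rule names are not reported here. Other list members given as examples, and single loci named elsewhere, were chosen after their values were seen. The 13 mitochondrially encoded genes of a fixed list were not analysed here either.

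Alternatives fixed beforehand were pseudocounts of 0.1 and 5, no filter and a filter of 5 FPKM, scaling to an equal sum and to the median ratio, summing loci of a name, a 4-fold limit and 10 level bins. Alternatives with strand-assigned loci only and with ratios centred on genes of like level were chosen after seeing the data. The procedure was tested on simulated data built from the 12405 genes of this comparison. Noise was normally distributed, with the size of the spread between the 2 libraries at like level but without its outlying genes. It is not replicate noise, so the shares that follow are no rates of error for these data. All 50 genes changed by each of 1.5, 2, 3 and 4 on the log2 scale were recovered, and 1.32% of unchanged genes passed the limit. Of 200 unchanged lists of 30 genes 5 stood apart, and all 20 lists shifted by 0.3 did. Unchanged lists were random draws set against random draws, so few could stand apart. Work was done in Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.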

Results

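Polyadenylated RNA was sequenced from SBC5, an established small cell lung cancer cell line, in 2 forms: the parental cells and a derivative selected for resistance to cisplatin, a platinum drug that crosslinks DNA. The resistant cells had been exposed to cisplatin at 1, 2, 4 and 20 µg/ml in turn. There was 1 library per group and therefore no replicates, so every difference given has no replicate check and describes these 2 libraries. The table listed FPKM, a fragment count scaled to locus length and library size, for 19217 loci. The values summed to 1019555 in the parental and 1081047 in the resistant library, and 17075 and 17574 loci reached 1 FPKM. The number of fragments behind each value is unknown, but the worth of 1 read was nearly equal in the libraries, with a resistant to parental ratio of 0.996.

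The comparison asked which transcripts differ between cisplatin-resistant and parental cells. SLC7A11, the cystine importer that supplies cysteine for glutathione, had the highest log2 ratio of the 12405 genes compared, at 4.56 with the pseudocount of 1. It had 3.05 FPKM in parental and 94.5 FPKM in resistant cells. It lies on chromosome 4 from 138164097 to 138242349 on the minus strand. The rank depended on the pseudocount: at 0.1 SLC7A11 had 4.91. Of the named genes, LOC439933 (7.11), STK31 (6.42), MECOM (5.52), NLRC5 (4.96) and SEMA3D (4.93) then lay above it. SEMA3D, a secreted semaphorin, had 1.54 FPKM in parental and 49.7 in resistant cells (log2 ratio 4.32), and MAP2, a neuronal microtubule-associated protein, had 10.4 and 163 FPKM (3.85). MECOM, a transcription factor gene of chromosome 3 (169083499 to 169663618), had 0.273 and 17.0 FPKM (3.82), and NTS, the precursor of the peptide neurotensin, had 1.41 and 33.0 FPKM (3.82). LRP1B had 10.8 and 101 FPKM (3.11), and ZNF414 had 6.88 and 96.0 FPKM (3.62). The other genes among the 15 highest were KIAA1804, COL11A1 (a fibrillar collagen chain), MYOF, LINC00472, CCDC148 and SLC40A1 (the iron exporter ferroportin), with log2 ratios from 3.07 for SLC40A1 to 3.41 for KIAA1804. STK31 and LOC439933 were listed at 0 in parental cells, and at 8.44 and 13.7 FPKM in resistant cells. The log2 ratio with a pseudocount of 5 was 2.06 for MECOM, 1.75 for SLC40A1, 1.66 for LINC00472, 1.64 for COL11A1 and 1.58 for CCDC148.

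ADAMTS6, a secreted metalloprotease, was lower in resistant cells, with 18.6 FPKM in parental and 1.09 FPKM in resistant cells (log2 ratio -3.23). TCEAL7 had 22.3 and 1.69 FPKM (-3.11), HECW2, a ubiquitin ligase, 10.3 and 0.399 FPKM (-3.02), and SLCO3A1, an organic anion transporter, 84.1 and 10.3 FPKM (-2.91). Among abundant transcripts, RGCC, a regulator of the cell cycle, had 214 FPKM in parental and 29.7 in resistant cells (-2.81), and RGS4, which shortens G protein signalling, had 142 and 19.6 FPKM (-2.79). The transcription factor gene RORB had 50.3 and 6.43 FPKM (-2.79). LINC01116, a noncoding RNA gene beside the HOXD cluster, had 58.8 and 8.61 FPKM (-2.64), and the joined TRIM6 and TRIM6-TRIM34 locus had 10.1 and 0.771 FPKM (-2.65). A pseudocount of 5 gave -1.95 for ADAMTS6, -2.03 for TCEAL7, -1.50 for HECW2 and -1.39 for the TRIM6 locus. SELE, the adhesion molecule E-selectin, was listed at 7.30 FPKM in parental and at 0 in resistant cells. Also among the 15 lowest, SLC30A1, PARS2, LINC00702 and FAM19A2 were represented by loci without an assigned strand. The strand-assigned locus of the zinc exporter SLC30A1 had 5.86 FPKM in parental and 1.44 in resistant cells, and that of PARS2 had 2.56 in both. LINC00702 had 5.95 and 1.21 FPKM there, and FAM19A2 had 23.8 and 11.1 FPKM. In the loci without a strand, PARS2 and LINC00702 were lower by the same 11.04-fold. Counts of few reads can give such equal ratios.

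By the fixed rule of size, 407 genes (3.28%) were at least 2-fold higher and 335 (2.70%) at least 2-fold lower in the resistant library, on the log2(FPKM + 1) scale, which understates the change of low genes. The other 11663 lay between. Loci without a strand, which stood for 414 of the genes compared, gave 65 of the higher and 39 of the lower genes. With strand-assigned loci only, an alternative chosen after seeing the data, 348 genes were higher and 304 lower. Across genes, Pearson's r of the log2 values was 0.963 and Spearman's rho was 0.960, where genes are not independent replicates. The median log2 ratio was -0.04, and -0.12 with sums scaled to be equal, and 95% of genes lay between -1.03 and 1.15. This range was -1.28 to 1.64 in the lowest of 20 bins of mean level, widest in the third lowest at -1.55 to 1.89, and -0.71 to 0.69 in the highest. The counts depended on the pseudocount, with 614 genes higher and 478 lower at 0.1 FPKM, and with 142 higher and 136 lower at 5 FPKM. Of the 86 genes past 2-fold that the naming rule chose, 52 stayed past it with a pseudocount of 5, and the log2 ratio moved by over 1.5 times in 44. With a pseudocount of 0.1 it moved so in 15.

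**Figure D1:**
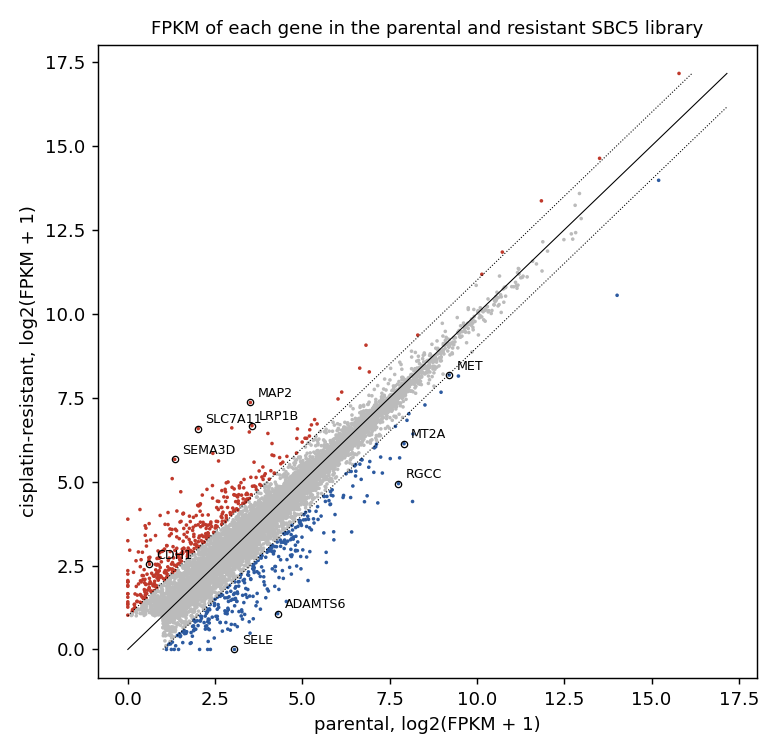
Each point is a gene, placed by log2(FPKM + 1) in the parental (x axis) and the resistant library (y axis). The solid line marks equal values, the dotted lines mark a log2 ratio of 1 and -1, and the 407 red and 335 blue points lie at or past them, among them SLC7A11 above and ADAMTS6 below.

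The fixed lists on the handling of platinum were examined first. MT2A and MT1X, metallothioneins that bind metals through their cysteines, were lower in resistant cells, with 240 and 69.0 FPKM for MT2A (log2 ratio -1.78) and 27.6 and 4.60 FPKM for MT1X (-2.35). The metal-responsive factor MTF1 had 6.97 and 8.67 FPKM (0.28). With 4 measured members, SLC30A1 included, the metallothionein list was too short for a comparison with random lists. The copper importer SLC31A1, which also carries platinum drugs, had 13.5 and 11.5 FPKM (-0.21), and SLC31A2 had 4.05 and 4.13 FPKM (0.02). The copper exporters ATP7A (14.4 and 11.3 FPKM, -0.33) and ATP7B (2.31 and 1.68 FPKM, -0.31) were also within 2-fold. None of the 13 measured platinum and copper transporters passed 2-fold, and the list median of 0.02, which turned to -0.04 with both libraries scaled to an equal sum and was 0.13 with a filter of 5 FPKM, lay at percentile 68.7 of random lists. None of the 7 measured genes of the ABC efflux list passed 2-fold. ABCC2, an exporter of drug conjugates, had 4.74 and 10.3 FPKM (0.97), and passed 2-fold with a pseudocount of 0.1 (1.10) and after division by the median ratio (1.01). ABCB1, ABCC1 and ABCG2 were not analysed here.

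Among 24 measured NRF2 targets, genes of the antioxidant response, 3 were at least 2-fold higher: SLC7A11, OSGIN1 (3.70 and 9.91 FPKM, 1.22, and 0.78 with a pseudocount of 5) and the thioredoxin reductase gene TXNRD1. TXNRD1 had 3677 and 10533 FPKM in a locus without a strand, and 80.1 and 174 FPKM (1.11) in its strand-assigned locus. NQO1 had 45.6 and 66.2 FPKM (0.53). The list median was 0.03, turned to -0.06 with sums scaled to be equal, and lay at percentile 97.6, short of the limit of 98, and passed it at 99.6, with a median of 0.07, under a filter of 5 FPKM. The 22 measured genes of glutathione synthesis and conjugation all lay within 2-fold, with a median of -0.08, and -0.14 with sums scaled to be equal, at percentile 39.3. GCLC, the catalytic subunit of the first step of glutathione synthesis, had 47.7 and 36.6 FPKM (-0.37), GCLM had 35.8 and 37.5 FPKM (0.07), and GSTP1 had 347 and 404 FPKM (0.22).

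DNA repair lists lay near other genes of like level. Medians were -0.07 for 25 nucleotide excision repair genes (percentile 37.6), -0.09 for 32 Fanconi anaemia and homologous recombination genes (18.7), -0.09 for 9 mismatch repair genes (35.9) and -0.06 for 11 translesion synthesis genes (39.6), and lay between -0.17 and -0.14 with sums scaled to be equal. ERCC1, part of the nuclease that cuts at platinum adducts, had 63.4 and 40.2 FPKM (-0.64), while its partner ERCC4 had 23.4 and 24.5 FPKM (0.06) and the damage-binding XPA had 10.2 and 9.63 FPKM (-0.07). BRCA1 had 27.9 and 20.3 FPKM (-0.44) and BRCA2 had 15.6 and 13.2 FPKM (-0.23). In these lists the 2-fold limit was passed by MRE11A alone, through a locus without a strand (15.1 and 85.4 FPKM), where its strand-assigned locus had 20.8 FPKM in both libraries. SLFN11 was not analysed here.

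Of 48 lists with at least 5 measured members, 14 stood apart from random lists matched on level, 8 of them higher and 6 lower. By chance 1.92 would lie past the limits if members varied together no more than random genes of like level. Members of a list can vary together, so 14 against 1.92 is no test. Scaling to an equal sum lowered each list median by 0.05 to 0.08 and turned the sign of 9, and division by the median ratio raised each by 0.03 to 0.04 and turned 3. The equal sum includes the MTRNR2L loci, which made up 6.84% of the parental and 16.2% of the resistant sum. Their reads are of uncertain source, so changes under that scaling depend in part on these loci. Measured epithelial genes were higher: the median of the 12 measured of 30 listed members was 0.69, above each of 10000 random lists. CDH1, the adhesion molecule E-cadherin, had 0.536 FPKM in parental and 4.81 in resistant cells (log2 ratio 1.92), CDS1 had 3.40 and 15.01 FPKM (1.86) and the tight junction gene TJP3 had 2.00 and 8.34 FPKM (1.64). Mesenchymal genes were lower, with a median of -0.28 over 16 of 30 listed members at percentile 0.21, 10 of the 16 below 0 and 6 above. ITGB3, an integrin chain, had 29.9 and 5.82 FPKM (-2.18), ZEB1, a repressor of CDH1, had 13.8 and 4.06 FPKM (-1.54), and CALD1 had 19.8 and 7.41 FPKM (-1.30). VIM, the intermediate filament vimentin, had 389 and 242 FPKM (-0.68). Of the 6 above 0, POSTN alone passed 2-fold, with 0.606 and 3.82 FPKM (1.59). A pseudocount of 5 made the epithelial and mesenchymal medians 0.43 and -0.18, and CDH1 (0.82), TJP3 (0.93), CALD1 (-0.996) and POSTN (0.65) no longer passed 2-fold. Fibroblast markers had a median of 0.34 over 9 of 18 listed members at percentile 99.8. All 6 measured collagens of that list lay above 0, with COL3A1 at 1.18 and 7.51 FPKM (1.97, and 1.02 with a pseudocount of 5), whereas the receptor PDGFRA had 48.0 and 10.1 FPKM (-2.14).

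YAP and TAZ targets, genes driven by coactivators that the Hippo pathway restrains, had a median of 0.30 over 24 members at percentile 99.99, and of 0.46 with a filter of 5 FPKM. MYOF (1.86 and 24.9 FPKM, 3.18) and CRIM1 (1.57 and 10.96 FPKM, 2.22, and 1.28 with a pseudocount of 5) passed 2-fold, 15 further members lay above 0 and 7 below, and YAP1 itself had 76.6 and 84.7 FPKM (0.14). Of 13 measured neuroendocrine markers, SCG2, a granule protein, passed 2-fold, with 109 and 20.1 FPKM (-2.38), and the list median of 0.18, which was 0.10 with sums scaled to be equal and 0.06 with a filter of 5 FPKM, lay at percentile 97.7. NEUROD1, POU2F3 and MYCN were not analysed here. Of the other factors that define subtypes of this cancer, SOX2 had 214 and 197 FPKM, REST 31.8 and 39.1 FPKM and NKX2-1 4.33 and 3.12 FPKM. SFN was the only measured squamous marker, at 19.8 and 45.3 FPKM (1.15). HBB (2.69 and 0.472 FPKM, -1.32, and -0.49 with a pseudocount of 5) and CORO1A (26.1 and 16.8 FPKM) were the 2 measured haematopoietic markers, and none of the 12 endothelial markers of the fixed list was measured.

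**Figure D2:**
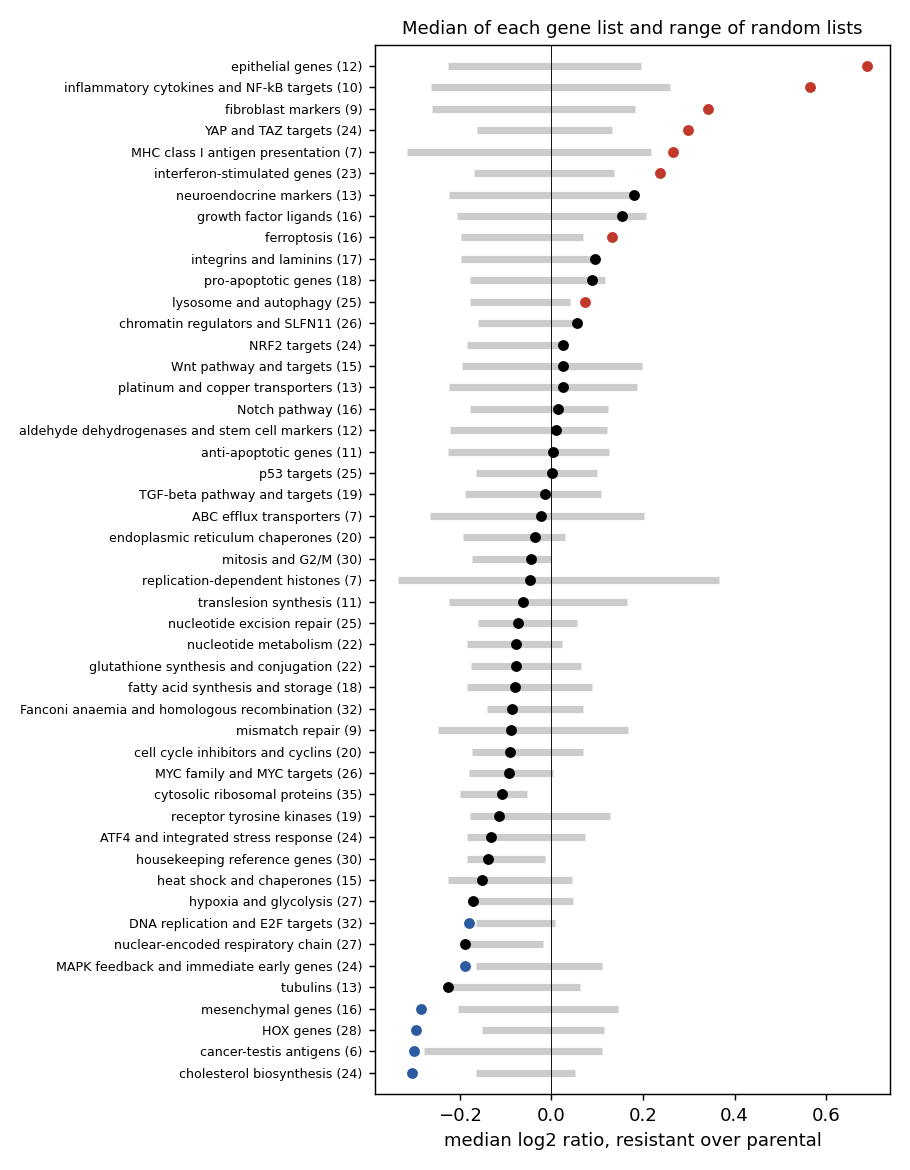
Points give the median log2 ratio, resistant over parental, of each of 48 gene lists, with the number of measured members in brackets, and grey bars span the central 95% of 10000 random lists matched on level. Red and blue points are the 8 lists at or above percentile 98 and the 6 at or below percentile 2, from epithelial genes at 0.69 to cholesterol biosynthesis at -0.30.

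Inflammatory cytokines and NF-kB targets were higher in resistant cells, with a median of 0.57 over the 10 measured of 31 listed members at percentile 99.9. PTGS2, the inducible cyclooxygenase, had 0.875 and 6.34 FPKM (1.97) and the inhibitor NFKBIA had 6.04 and 11.1 FPKM (0.78), while the cytokine CSF1 had 3.59 and 1.25 FPKM (-1.03). Interferon-stimulated genes had a median of 0.24 over 23 members at percentile 99.9, with 17 members above 0. IFITM3, which restricts viral entry, had 28.0 and 93.9 FPKM (1.71) and the RNA sensor IFIH1 had 0.947 and 5.11 FPKM (1.65). MX1 was listed at 0 in parental and at 2.16 FPKM in resistant cells. IFITM2 had 21.7 and 10.0 FPKM (-1.04), and -0.91 with loci of a name summed. The 7 measured of 17 listed genes of MHC class I antigen presentation had a median of 0.27 at percentile 98.4. NLRC5, the regulator of these genes, was listed at 0 in parental and at 3.02 FPKM in resistant cells. The MHC list stood apart in 7 of 10 settings: it moved to percentile 97.5 with a pseudocount of 5, had too few members with a filter of 5 FPKM, and moved to 94.0 with only strand-assigned loci, an alternative chosen after seeing the data. The medians of the inflammatory and MHC lists were 0.29 and 0.15 with a pseudocount of 5, where PTGS2 (0.95), CSF1 (-0.46), IFIH1 (0.76), MX1, NLRC5 and IFITM2 (-0.83) lay within 2-fold.

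MET, the receptor of hepatocyte growth factor, had 589 FPKM in parental and 288 in resistant cells (log2 ratio -1.03), and EGFR had 1.45 and 7.35 FPKM (1.77). RET had 0.393 and 2.96 FPKM (1.51) and ROR1 had 5.08 and 1.38 FPKM (-1.35), and the 19 measured receptor tyrosine kinases had a median of -0.11, and -0.18 with sums scaled to be equal, at percentile 12.9. Among 16 growth factor ligands (median 0.15, percentile 93.9), FGF5 had 1.59 and 0.0790 FPKM (-1.26), KITLG 11.3 and 4.41 FPKM (-1.18) and TGFA 0.739 and 2.64 FPKM (1.06, 0.99 with sums scaled to be equal), and PDGFB was listed at 0 in parental and at 1.57 FPKM in resistant cells. MAPK feedback and immediate early genes were lower as a list, with a median of -0.19 over 24 members at percentile 1.13. DUSP6, a phosphatase induced by ERK, had 91.2 and 44.5 FPKM (-1.02), while JUN had 5.52 and 13.0 FPKM (1.11). MET and DUSP6 moved just inside 2-fold when the resistant library was divided by the median ratio, and the MAPK list moved to percentile 3.30 and a median of -0.12 with a pseudocount of 5, whereas a filter of 5 FPKM gave a median of -0.31. Under the pseudocount of 5, EGFR (0.94), RET (0.56), ROR1 (-0.66), FGF5 (-0.37), KITLG (-0.79), TGFA (0.41), PDGFB, DUSP6 (-0.96) and JUN (0.78) lay within 2-fold. A filter of 5 FPKM turned the median of the ligands to -0.06. AXL was not analysed here.

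Cholesterol biosynthesis genes were lower together: each of the 24 measured members lay below 0, none passed 2-fold, and the median of -0.30 was below all 10000 random lists. STARD4 had 13.2 and 6.28 FPKM (-0.96) and the feedback regulator INSIG1 had 29.2 and 17.0 FPKM (-0.75). Among 18 genes of fatty acid synthesis and storage (median -0.08, percentile 32.8), the activating enzyme ACSL3 had 19.6 and 8.59 FPKM (-1.10) and the desaturase SCD had 136 and 64.7 FPKM (-1.06). Ferroptosis genes had a median of 0.13 over 16 members at percentile 99.6, and of 0.05 with sums scaled to be equal. SLC7A11 and SLC40A1 (0.900 and 14.9 FPKM) passed 2-fold and GPX4, which reduces lipid peroxides, had 320 and 390 FPKM (0.28). Lysosome and autophagy genes had a median of 0.07 over 25 members at percentile 99.5, which became -0.01 with sums scaled to be equal, and CTSZ had 1.42 and 0.164 FPKM (-1.06). Both ACSL3 (-0.86) and CTSZ (-0.31) lay within 2-fold with a pseudocount of 5, and with a filter of 5 FPKM the median of fatty acid genes was -0.14.

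Hypoxia and glycolysis genes had a median of -0.17 over 27 members at percentile 3.45. SLC2A3, a glucose transporter, had 7.69 and 1.71 FPKM (-1.68), ALDOC 18.97 and 5.81 FPKM (-1.55) and the peptide precursor ADM 2.26 and 10.3 FPKM (1.79). Genes of the ATF4 stress response had a median of -0.13 over 24 members at percentile 11.9: SLC7A11 was higher, DDIT4 had 6.20 and 1.91 FPKM (-1.31), and ATF4 had 231 and 177 FPKM (-0.38). Tubulins and associated proteins, at a median of -0.23 over 13 members and percentile 2.58, held TUBA1A with 501 and 201 FPKM (-1.31), while MAP2 of that list was higher (3.85). The medians of tubulins and ATF4 genes were -0.09 and -0.07 with a pseudocount of 5, where SLC2A3 (-0.92) and DDIT4 (-0.70) lay within 2-fold, and ADM was at 1.07. In the heat shock list (median -0.15, percentile 20.2), DNAJA4 had 15.3 and 2.35 FPKM (-2.28) in its only locus, which had no strand. That value may rest on few reads.

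DNA replication and E2F target genes had a median of -0.18 over 32 members at percentile 1.06, with none past 2-fold; the helicase subunits MCM5 (87.3 and 67.2 FPKM, -0.37) and MCM2 (106 and 83.8 FPKM, -0.34) were examples. A pseudocount of 5 moved this list to percentile 2.19. The 30 measured genes of mitosis had a median of -0.04 at percentile 84.5. RB1 had 40.2 and 29.1 FPKM (-0.45), MYC 44.2 and 43.1 FPKM (-0.03), MYCL 4.69 and 3.86 FPKM (-0.23) and EZH2 89.99 and 81.7 FPKM (-0.14). The 25 measured p53 targets had a median of 0.00, and of -0.08 with sums scaled to be equal, at percentile 71.2. PLK2 had 138 and 68.3 FPKM (-1.01), just inside 2-fold after division by the median ratio, and the inhibitor CDKN1A had 1.66 and 2.54 FPKM (0.42). Of the survival genes, BCL2A1 had 6.55 and 2.75 FPKM (-1.01, and -0.98 after division by the median ratio), BCL2 2.02 and 2.52 FPKM (0.22), BCL2L1 19.3 and 22.7 FPKM (0.23) and MCL1 119 and 100 FPKM (-0.25). Cancer-testis antigens had a median of -0.30 over 6 of 32 listed members at percentile 1.64, with MAGEA4 at 627 and 446 FPKM (-0.49). In the remaining lists, HES2 (Notch) had 1.15 and 3.82 FPKM in a locus without a strand and 1.32 and 2.56 FPKM (0.62) in its strand-assigned locus, within 2-fold. DKK1 had 4.04 and 9.36 FPKM (1.04, and 0.96 with sums scaled to be equal) and WNT7B 0.531 and 2.54 FPKM (Wnt), BMP4 3.31 and 0.901 FPKM (TGF-beta), ITGB4 2.51 and 6.52 FPKM (integrins) and CD24 4.84 and 17.7 FPKM (stem cell markers). With a pseudocount of 5, PLK2 (-0.97), BCL2A1 (-0.57), HES2 (0.52), DKK1 (0.67), WNT7B (0.45), BMP4 (-0.49) and ITGB4 (0.62) lay within 2-fold. Genes used as housekeeping references had a median of -0.14 over 30 members at percentile 18.7.

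HOX genes, which encode factors that set position along the body axis, differed by cluster. The 6 measured HOXD genes had a median log2 ratio of -1.10, with 5 at least 2-fold lower, and the 8 HOXB loci had a median of -0.99, with 4 at least 2-fold lower. The count in HOXD fell to 3 after division by the median ratio and to 0 with a pseudocount of 5, which left 2 in HOXB and gave HOXD a median of -0.50, HOXD9 -0.83 and HOXD11 -0.49. The 8 HOXA loci had a median of 0.19 and the 6 HOXC loci a median of -0.06. HOXB8 (chromosome 17, 48611377 to 48614939) had 27.0 and 6.74 FPKM (-1.85) and HOXB9 had 54.4 and 18.9 FPKM (-1.48). HOXD9 (chromosome 2, 176122720 to 176124937) had 9.15 and 2.96 FPKM (-1.36), and HOXD11 had 2.76 and 0.527 FPKM (-1.30). HOXA13, in a locus without a strand, was the only measured HOXA gene past 2-fold, with 3.70 and 1.23 FPKM (-1.08), and its strand-assigned locus had 1.90 and 0.834 FPKM (-0.66). Over all 28 loci the median was -0.30, below each random list.

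**Figure D3:**
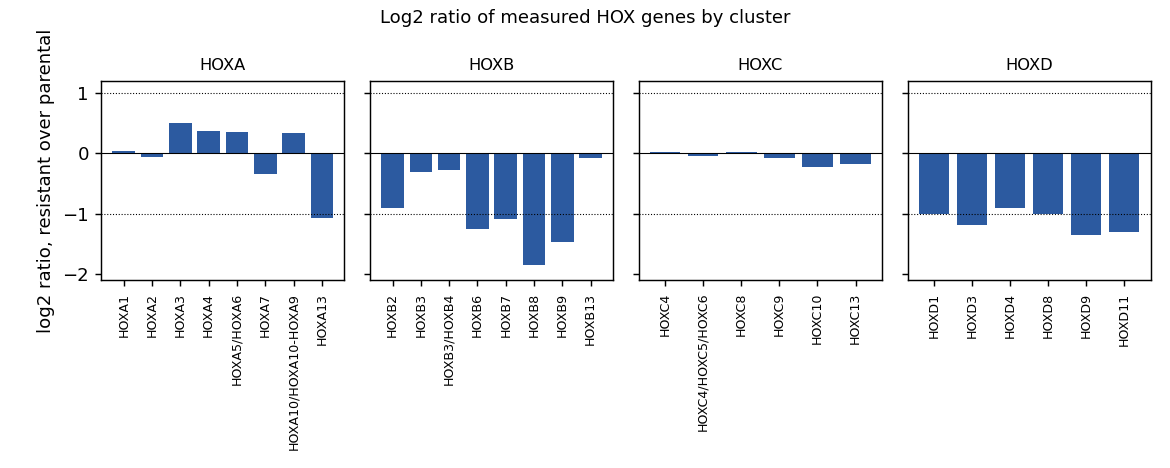
Bars give the log2 ratio, resistant over parental, of each measured HOX locus, grouped by cluster in gene order, with joined names for loci that hold several genes and dotted lines at 1 and -1. Bars reach -1.85 in HOXB and -1.36 in HOXD, while HOXC bars stay between -0.23 and 0.03.

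A last comparison asked whether neighbouring genes differed together, since selection can change chromosome number. The strongest run of 50 neighbouring genes lay at the end of the long arm of chromosome 19, from 56397966 to 58457833, where 47 of 50 genes lay above 0 and the median log2 ratio was 0.40 (95% interval of the median across genes 0.33 to 0.49). Zinc finger genes made up 46 of the 50 loci. The lowest run lay on chromosome 1 from 174999163 to 196609225, with 45 of 50 genes below 0 and a median of -0.37 (-0.41 to -0.26), which was -0.24 with a pseudocount of 5. On chromosome 1 the 489 genes after the largest gap in gene positions, from 144 Mb on, had a median of -0.22 (-0.26 to -0.19), and the 703 genes before it, up to 122 Mb, had a median of 0.01 (-0.02 to 0.03), which turned to -0.07 with sums scaled to be equal, a split chosen after the values were seen. Further low runs lay on chromosome 17 from 44924709 to 49583827, which holds HOXB, with a median of -0.31, on chromosome 9 from 128455186 to 132946874 (-0.30) and on chromosome 15 from 71096952 to 77485607 (-0.29). All 8 runs chosen as farthest from 0 without overlap, out of 10570, lay beyond the range of 100 shuffles of ratios among genes of like level, which reached -0.26 and 0.23. With shuffles repeated under 8 alternatives, a check chosen after seeing the data, the number beyond the range fell to as few as 4 of the 8, with a pseudocount of 0.1, and stayed at 8 in 3 alternatives. The chromosome 19 run was at 0.18 with a pseudocount of 5, where shuffles reached 0.15, and a filter of 5 FPKM left 22 of its genes, with a median of 0.46, too few for the range of 50-gene runs. By whole chromosome, the lowest medians were -0.20 for the 389 genes of chromosome 15 and -0.16 for the 694 genes of chromosome 17, and the highest was 0.08 for the 864 genes of chromosome 19, which was 0.01 with sums scaled to be equal and 0.12 after division by the median ratio. Genes are not replicates, and RNA is an indirect readout of copy number.

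**Figure D4:**
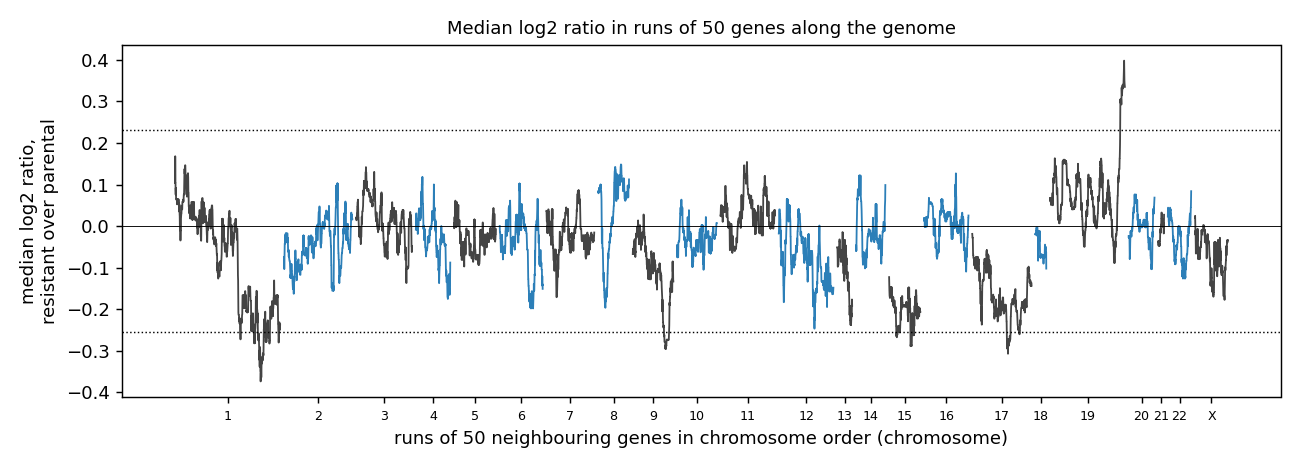
The line gives the median log2 ratio, resistant over parental, of each run of 50 neighbouring genes, ordered along chromosomes 1 to 22 and X, and dotted lines mark the extremes of 100 shuffles, -0.26 and 0.23. The end of chromosome 19 reaches 0.40 and the second part of chromosome 1 reaches -0.37.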

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

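Loci without a gene name were used in no comparison of genes. Of 2729 loci without a gene name and with at least 1 FPKM in either library, 229 (8.39%) were at least 2-fold higher in resistant cells than in parental cells and 275 (10.1%) at least 2-fold lower, against 2.94% and 2.55% of named strand-assigned loci and 12.1% and 5.79% of 3573 named loci without a strand. Of these unnamed loci 2320 had no assigned strand, as did 208 of the 229. The unnamed locus with the highest ratio had 3.78 FPKM in parental and 94.1 FPKM in resistant cells. While 24 unnamed loci were listed at 0 in parental and at 1 FPKM or more in resistant cells, 23 were listed the other way round. No explanation was tested for them.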

How the results depend on the processing

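Strand-assigned loci only and centring on genes of like level were chosen after seeing the data; the rest were fixed before. The counts of 407 genes higher and 335 lower became 142 and 136 with a pseudocount of 5 and 76 and 60 at a 4-fold limit, and 614 and 478 with a pseudocount of 0.1. A larger pseudocount or limit calls fewer genes by construction. Scaling to an equal sum gave 351 higher and 379 lower, median ratio scaling 425 and 308, and strand-assigned loci only 348 and 304. The correlation across genes of 0.963 was 0.946 and 0.974 with pseudocounts of 0.1 and 5, 0.952 with a filter of 5 FPKM and 0.965 with strand-assigned loci, and the cause was not tested. Of the 14 lists that stood apart, 11 did so in each of the 10 settings. A filter of 5 FPKM left MHC class I with too few members and put NRF2 targets at 99.6, TGF-beta genes at 99.9 and hypoxia genes at 0.82, past the limits, as did a pseudocount of 5 for hypoxia (1.495) and no filter for neuroendocrine markers (98.1). With a pseudocount of 5 the percentiles of DNA replication, MHC class I and MAPK genes were 2.19, 97.5 and 3.30, and with strand-assigned loci MHC class I was at 94.0; the cause was not tested. The highest run of 0.40 became 0.18 with a pseudocount of 5. With a filter of 5 FPKM the highest run was 0.25, while the 22 genes left of the chromosome 19 run had a median of 0.46. The lowest run of -0.37 was -0.24 with a pseudocount of 5 and -0.44 with sums scaled to be equal. Of 911 values of named genes in alternatives, 865 stayed on their side of the 2-fold limit in the same direction, 42 no longer passed it, 34 of them with a pseudocount of 5, and 2 passed it newly. The 865 include 114 values with no filter and 114 with a filter of 5 FPKM. These could not move, since a filter does not change a gene's own ratio. With loci summed, only names with several loci could move. With strand-assigned loci only, just the genes represented by a locus without a strand could. Most values in these settings were therefore fixed as well, and the 865 are no measure of robustness. MRE11A at -0.00083 and PARS2 at 0.0010 changed sign with strand-assigned loci, where both were near 0, since another locus stood for them. Unknown depth limits all values, most of all those of low genes.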

Other observations

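The patterns weighed below were picked from these same data, so every test of them came after its pattern was seen. Tests of scaling, of NRF2 activity, of the HOX clusters and of the chromosome end were also chosen after the results were seen. The locus of highest FPKM in the table belonged to MTRNR2L1, a nuclear copy of a mitochondrial ribosomal RNA gene, at 56508 FPKM in parental and 146228 FPKM in resistant cells. The MTRNR2L loci together made up 6.84% of the summed FPKM in parental and 16.2% in resistant cells. Such copies share reads with the mitochondrial genome, so the source of these reads is uncertain. Scaling to an equal sum includes the MTRNR2L loci, so the shifts and turned signs given under it depend in part on them. Integrin and laminin genes of the fixed list went both ways around a median of 0.10 (percentile 96.8), which turned to -0.10 with a filter of 5 FPKM and was 0.03 with sums scaled to be equal: ITGAV had 184 FPKM in parental and 331 in resistant cells, LAMB2 28.7 and 52.0 FPKM, LAMB1 138 and 74.1 FPKM and ITGA5 11.9 and 5.64 FPKM.

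SLC7A11 was higher by 4.56 on the log2 scale in resistant cells. Scaling between the libraries would move every gene, and the median log2 ratio over all genes was -0.037. Since FPKM are already scaled to library size, a median near 0 was largely given beforehand. It shows only that no shift common to all genes makes up the 4.56. A gain of the surrounding chromosome segment was argued against by the other 14 expressed genes within 5 Mb, whose median was -0.16 and highest value 0.64, though a gain of this gene alone was not tested. Raised NRF2 activity cannot be told apart from its absence: the other 23 measured targets had a median of -0.016, with 11 above and 12 below 0, while TXNRD1 and OSGIN1 were higher. Resistance itself may go with the higher SLC7A11, and with 1 library of each kind a difference between cultures stays open as well.

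HOXB and HOXD genes were lower as clusters while HOXC genes and HOXA genes other than HOXA13 were within 2-fold, which a loss of chromosome segments or a trend with level might produce. Other genes within 3 Mb had medians 0.80 above that of HOXB (57 neighbours, median -0.20) and 1.08 above that of HOXD (26 neighbours, median -0.02). This argues against a loss of the wider segment as the whole cause, though a loss confined to either cluster was not tested. After subtracting the median of genes of like level, the 14 HOXB and HOXD loci still had a median of -1.03. The level medians lay only between -0.13 and 0.10, so this outcome was fixed beforehand and was no test. A trend of that size is too small to make up the difference. A regulatory difference local to these clusters is a hypothesis drawn from these same data, left open and not tested. A chance difference between the cultures was not tested.

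The run at the end of chromosome 19 was higher, with a median of 0.40, and of 0.18 with a pseudocount of 5, where shuffles reached 0.15. After subtracting the median of genes of like level it was still 0.37 (95% interval 0.30 to 0.46). Those level medians lay only between -0.13 and 0.10, so the subtraction could not have removed the difference and was no test. It shows only that a trend of that size is too small to make up the run. A shift of zinc finger genes in general was argued against by the 252 such genes on other chromosomes, with a median of -0.054, and the 134 elsewhere on chromosome 19 had a median of 0.08. A gain of the chromosome end cannot be told apart from a local change in the zinc finger cluster: the 8 genes past the run that are not zinc finger genes had a median of 0.10 (-0.05 to 0.35), too few to decide, while the 4 such loci inside the run lay between 0.18 and 1.04. An earlier form of this test, on loci inside the run, met the value set beforehand for a gain, but it was replaced because some of its loci were joined with zinc finger genes and all belong to the pattern.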
